A study of Mus musculus with 5 samples.

How the data were processed

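Gene expression was measured in mouse embryonic fibroblasts (MEFs) that lack the endogenous STING gene and were reconstituted with the R284S variant of STING, the adaptor protein that carries the cytosolic DNA-sensing signal to TBK1 and IRF3. Per the labels, the cells were treated for 9 hours with vehicle, Compound C, doxorubicin, GSK 690693 or tofacitinib, and total RNA was extracted with a silica column kit. From each sample 300 ng of RNA was converted to labelled cDNA with a whole-transcript Affymetrix kit and hybridised to 1 array, so the series holds 5 arrays and 1 array per group. The doses are not given in the sources used here, and no label names a separate culture, batch or scan.

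The authors deposited 1 log2 signal per probe set and array, and per the submitters' processing notes the values were made with Affymetrix Expression Console 1.3.1.187. The summarisation, background correction, normalization between arrays and any filter are not given in the sources used here. The log base was inferred from the deposited values, which ran from 1.05 to 13.18 over the 5 arrays. If a quantile step was part of the authors' processing, a shift of most genes in one direction would have been removed before deposit. No detection call was used here, so whether a dim probe set lay above background is unknown, and differences between dim values may be understated if background signal remains in them.

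The deposited table held 41345 probe sets, and 0 value columns were left unused. Gene symbols came from the platform annotation. Of the probe sets, 23521 had 1 symbol, 1814 had several and 16010 were not listed with a gene. Probe sets with several symbols were named for none of them and not analysed here, and those not listed were only counted. The Entrez identifiers of 23328 of the 23521 single-symbol probe sets were found in a table of RefSeq genes of the assembly GRCm38.p6, which was used for older symbols only. The genome build of the array was not named, so no coordinates are printed. The single-symbol probe sets covered 22180 genes, of which 1082 had more than 1 probe set. Those genes were represented by the probe set with the highest mean over the 5 arrays. A gene was tested for size of difference if the highest of its 5 values reached the median of that array over the single-symbol probe sets, which lay between 5.37 and 5.44, and 12317 genes did.

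Differences are log2 signal on a compound array minus log2 signal on the vehicle array, or on another compound array, and genes were counted at an absolute difference of 1 or more, which is 2-fold. With 1 array per group there is no spread between samples, no test and no p-value, and none of the differences has a replicate check. The spread between the closest pair of arrays by standard deviation served as a yardstick, since it is an upper limit to the noise between the arrays of that pair. The number of arrays limits the precision. A total of 31 gene lists was written before the data were examined. They cover interferon, NF-kB and JAK-STAT genes, stress, cell cycle and metabolic programmes, growth factor responses and markers of other cell types. A list is described by the median log2 difference of its tested members, by the number of members at least 1.5-fold higher or lower, and by where its median falls among the medians of 10000 random lists of the same size, drawn from 20 bins of mean signal. Lists with fewer than 5 tested members were not summarised, which applied to 2 lists. The position among random lists describes these arrays and not the conditions.

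Genes are named by a rule fixed before the data were examined. It takes the 10 largest differences each way among genes at least 2-fold apart from vehicle, leaving out small RNA genes and genes without a descriptive symbol, the 5 members of each list with the largest absolute difference, and the 5 largest differences each way between compounds. It also takes a fixed set holding 6 interferon and cytokine genes, the STING gene, the AMPK subunit genes, Ulk1, Akt1, Jak1 and Top2a. Because all 4 compounds were compared with the same vehicle array, correlations between their differences are set beside the value simulated for unchanged arrays, and correlations of differences that share no array are given as well. Overlaps are set beside the overlap of independent lists of the same lengths and, in a simulation added after the data were seen, beside that of unchanged arrays.

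The counting and the list step were tested on simulated data, in 10 runs with 200 changed genes among 12317. The noise was normal, with the spread of the closest pair of arrays. For one compound array against vehicle, 7.2% of the genes changed 1.5-fold were counted at the 2-fold threshold, 50.2% of those changed 2-fold, 97.4% of those changed 3-fold and 100.0% of those changed 4-fold, and on average 1.6 unchanged genes were counted. The last number may be too low for real arrays. Noise drawn from the differences of that pair, which may hold effects of both its compounds, gave 18.32 higher and 18.65 lower genes. A simulated list of 40 genes had a median percentile of 34.9 without a shift and of 100 with a log2 shift of 0.3. The alternatives were quantile normalization of the deposited values, centring each array on its median, 3 other filters on low values, the median of the other 4 arrays in place of vehicle, the mean of a gene's probe sets, a 1.5-fold threshold and the mean in place of the median of a list. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.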

Results

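The data come from 5 arrays of STING-deficient mouse embryonic fibroblasts that express the R284S variant of STING, a gain-of-function form of the adaptor. One array was hybridised per treatment, with RNA taken 9 hours after vehicle, Compound C, doxorubicin, GSK 690693 or tofacitinib. Compound C, also called dorsomorphin, inhibits the energy-sensing kinase AMPK and BMP type I receptors. Doxorubicin is an anthracycline that poisons topoisomerase II, GSK 690693 inhibits AKT kinases and also AMPK, and tofacitinib inhibits JAK kinases. The submitters describe the treatment as AMPK inhibitors in STING-driven inflammation, so the question put to each compound was which transcripts, and which inflammatory ones, differed from vehicle. The median log2 signal over the 12317 tested genes was 7.22 for vehicle, 7.16 for Compound C, 7.16 for doxorubicin, 7.29 for GSK 690693 and 7.39 for tofacitinib. No group had a replicate, so every difference is one between single arrays, without an error. Values in parentheses after gene names are log2 differences from vehicle unless another array is named, and members of a list are counted as higher or lower at 1.5-fold.

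By the standard deviation of the log2 difference over tested genes, GSK 690693 and tofacitinib gave the closest pair of arrays, at 0.258. By the 99th percentile of the absolute difference, vehicle and tofacitinib were slightly closer, at 0.82 against 0.83. Vehicle lay at standard deviations of 0.295 from tofacitinib, 0.306 from GSK 690693, 0.455 from Compound C and 0.584 from doxorubicin. Centring each array on its median moved the median difference of tofacitinib from vehicle from 0.09 to −0.08, so list medians for that compound are read against matched random lists.

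Several interferon-stimulated genes were bright on the vehicle array. The cells of all 5 arrays carried R284S, so whether this signal depended on the variant cannot be seen here. Cxcl10, a chemokine induced by interferon, had a log2 signal of 12.47, Ifit1 11.61 and Isg15 10.71, and the chemokine gene Ccl5 stood at 12.96 in a range that ended at 13.18. Ifnb1, the gene of interferon beta, read 2.86 on the vehicle array and between 2.56 and 2.88 on the others, below the filter on all 5. The probe set of the STING gene, Sting1, read 5.12 with vehicle and between 5.07 and 5.25 with the compounds, also below the filter. It interrogates the mouse gene and may lie outside the disrupted or introduced sequence, so it checks neither the knockout nor the reconstitution. Among the AMPK subunits, Prkaa1 (catalytic alpha 1) read 10.67 with vehicle, 9.97 with Compound C, 10.22 with doxorubicin, 10.52 with GSK 690693 and 10.50 with tofacitinib. Prkaa2 (catalytic alpha 2) read 6.16 with vehicle and 8.81 with Compound C, a 6.28-fold difference, against 7.18, 6.99 and 6.86 with doxorubicin, GSK 690693 and tofacitinib. Among the regulatory subunits, Prkab1, Prkab2, Prkag1 and Prkag2 lay within 0.39 of vehicle with each compound, and Prkag3 was below the filter. Ulk1, the autophagy kinase that phosphorylates STING, read 8.82 with vehicle and 9.38 with Compound C. Of the other drug targets, Akt1 differed most with doxorubicin, by 0.53, and Jak1 with doxorubicin, by 0.30. Top2a differed by −0.92 with Compound C, −0.80 with doxorubicin, 0.08 with GSK 690693 and 0.42 with tofacitinib.

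**Figure D1:**
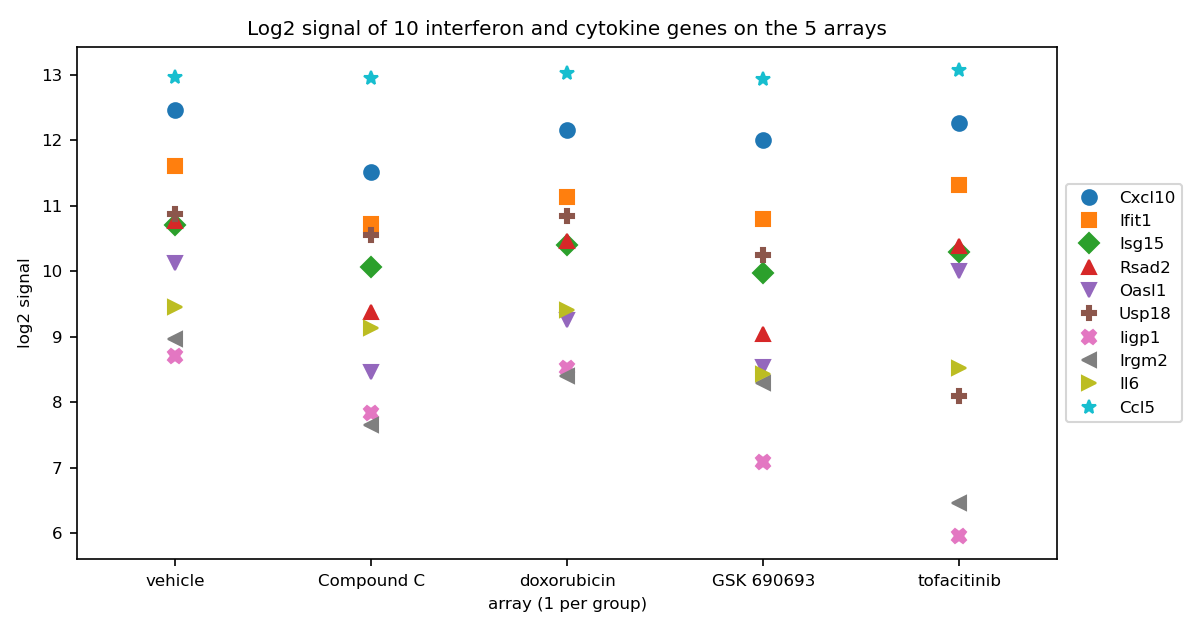
Log2 signal (vertical axis) of 10 interferon and cytokine genes on the 5 arrays (horizontal axis), 1 point per gene and array. Usp18 stands at 10.87 with vehicle and 2.77 log2 units lower with tofacitinib, while Ccl5 lies between 12.93 and 13.07 on all 5 arrays.

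With Compound C, interferon-stimulated and BMP-responsive transcripts read lower than with vehicle, and sterol synthesis, amino acid stress and lysosome transcripts read higher. In all, 160 genes were at least 2-fold higher and 311 at least 2-fold lower. The largest difference was in Eid3, an inhibitor of EP300 and a component of the SMC5/6 complex, which was 20.3-fold higher (log2 4.34). It was followed by Tmem236 (2.92), Tbc1d8 (2.90), Csnka2ip (2.87), Prkaa2 (2.65), the epidermal transcription factor Grhl3 (2.17), the death-associated kinase Dapk1 (2.05), the stem cell factor gene Kitl (2.04), the cystine transporter Slc7a11 (2.0) and Zfp972 (1.97). The lowest against vehicle were Tasor, a subunit of the HUSH silencing complex (−2.84), the G protein regulator Rgs4 (−2.71), Trim30d (−2.66), the hyaluronan synthase Has2 (−2.58), the BMP-responsive factor Atoh8 (−2.29), Plekhg2 (−2.22), Ankrd49 (−2.21), Dhrs9 (−2.18), Trim30a (−2.17) and the proteasome assembly chaperone Psmg2 (−2.08). Of these, Slc7a11 and Psmg2 have a second probe set each, which read 0.18 and −0.01 with Compound C. On the probe set used, Slc7a11 also read above vehicle with doxorubicin (0.94), GSK 690693 (1.01) and tofacitinib (0.91).

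Of 74 tested interferon-stimulated genes, 29 were at least 1.5-fold lower with Compound C and 0 at least 1.5-fold higher, and 63 lay below vehicle by any amount. The list median was −0.48, below all 10000 random lists, and −0.14 with the median of the other 4 arrays as reference, which itself holds GSK 690693 and tofacitinib. Trim30d, Trim30a, the RNA sensor Tlr3 (−1.84), Apol9b (−1.67) and Oasl1 (−1.66) differed most. Trim30d and Trim30a read higher with vehicle than on any other array. Against the median of the other 4 arrays they stood at −1.285 and −1.125 with Compound C. Of 16 tested type I interferon and early IRF3-dependent genes, 5 of which also belong to the interferon-stimulated list, 5 were at least 1.5-fold lower and the median was −0.32, with 37 of 10000 random medians at or below it. They included Ccl4 (−1.27), Cxcl10 (−0.95), Ifit1 (−0.89) and Isg15 (−0.64). The 44 NF-kB dependent inflammatory genes went both ways, with 5 higher, 9 lower and a median of −0.15. The adhesion molecule gene Icam1 was higher by 1.3 and Cd44 by 0.91, whereas Il1a was at −1.03 and the NF-kB inhibitor gene Nfkbia at −0.88. Il6 differed by −0.32. The JAK-STAT feedback list had a median of 0.30 over 19 genes, with Cebpd at 1.60 and Socs2 at 0.92 on one probe set and 0.20 on another.

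The BMP and SMAD1/5/9 list had the lowest median with Compound C, −0.72 over 22 genes, of which 11 were at least 1.5-fold lower and 0 higher. Its members Id1 (−1.83), Smad9 (−1.62) and Smad6 (−1.35) are target or feedback genes of BMP receptors, and Hes1 (−1.80) was also on the list. Extracellular matrix and YAP target genes had a median of −0.04 over 50 genes, 0.03 after centring, in which Ankrd1 (−1.81) and Ccn2 (−1.59) were lowest, although a second probe set of Ccn2 read −0.07. Mitosis genes were lower, with 21 of 60 at least 1.5-fold down, 0 up and a median of −0.45. They included Kif23 (−1.24) and the mitotic kinase Plk1 (−1.20). DNA replication genes had a median of −0.20 over 52 genes, with 12 lower and 1 higher, among them Prim1 (−1.42) and Pola2 (−1.27). Ribosome biogenesis and MYC target genes had a median of −0.16, with Myc itself at −1.05.

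Several metabolic lists lay on the other side of vehicle with Compound C. Cholesterol and fatty acid synthesis genes, targets of SREBP, had a median of 0.37, with 13 of 34 at least 1.5-fold higher and 2 lower. Lpin1 (1.96), Insig1 (1.68), the squalene epoxidase gene Sqle (1.51) and Stard4 (1.39) led. The ATF4 list of amino acid and integrated stress response genes had a median of 0.29, with 13 of 48 higher and 1 lower, including Ppp1r15a (1.5), Slc7a3 (1.3) and Atf4 (1.09). FOXO target genes had a median of 0.38 over 35 genes, with Ypel2 (1.5), Foxo3 (1.37) and Irs2 (0.96). Lysosome and autophagy genes had a median of 0.32 over 56 genes, 8 of them higher, 1 lower and 48 above vehicle by any amount, with Fnip2 (1.26), Atg14 (1.24) and Hmox1 (1.11). Each of these 4 medians exceeded all 10000 random lists. Positive medians were also found for glycolysis and hypoxia genes (0.27), the NRF2 antioxidant list (0.28), oxidative phosphorylation (0.22) and ribosomal proteins (0.29). The p53 target list had a median of 0.13, with 15 of 51 higher and 6 lower and with Perp (1.77), Slc19a2 (1.5) and Gtse1 (1.48) at its head. Immediate early genes had a median of 0.12, in which the nuclear receptors Nr4a1 (1.81), Nr4a3 (1.40) and Nr4a2 (1.33) were higher and Hbegf (−1.46) and Plaur (−1.43) lower. Median differences for heat shock (−0.11), unfolded protein response (0.03), histone (0.12), numbered zinc finger (−0.02) and STING and AMPK pathway genes (−0.06) lay inside the central 95% of random lists.

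**Figure D2:**
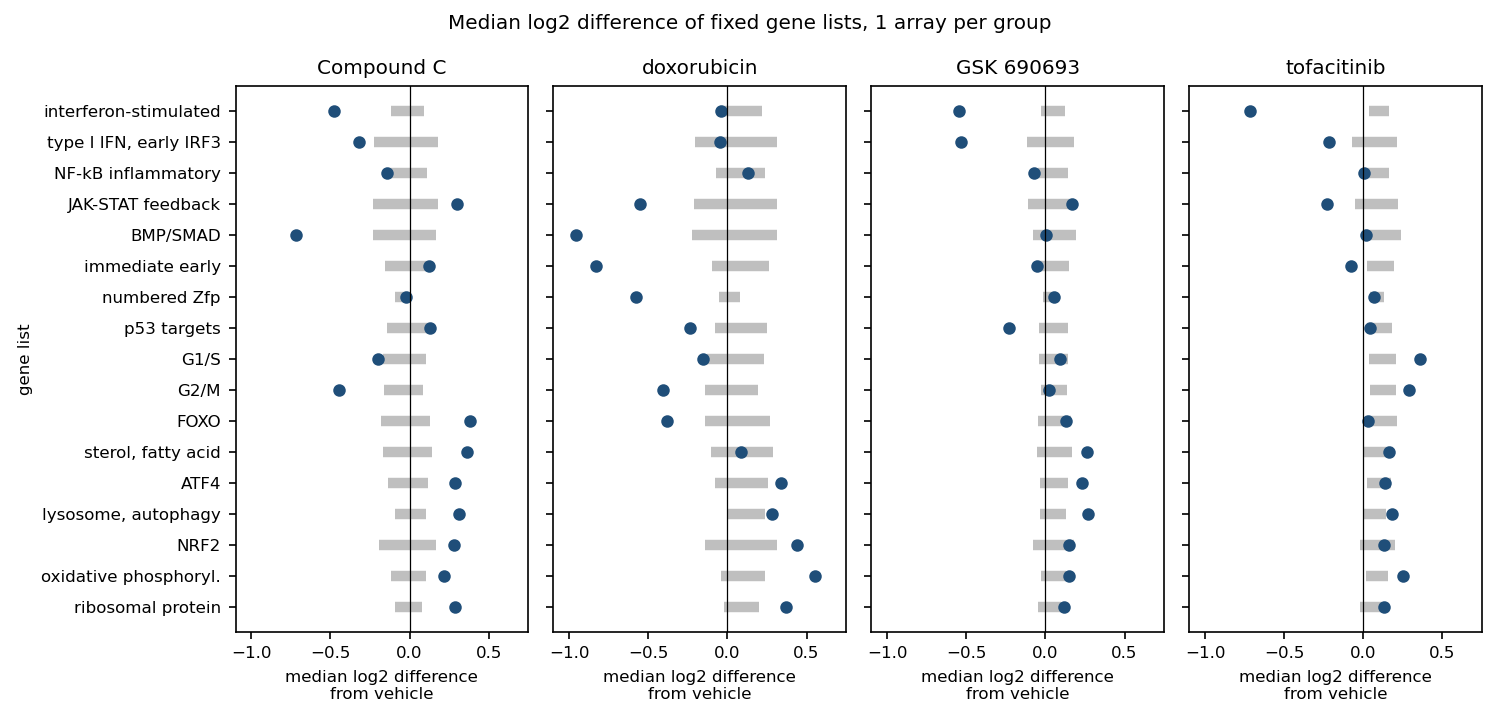
Median log2 difference from vehicle (horizontal axis) of 17 gene lists (vertical axis) for each compound, with 1 array per group. Points are list medians and grey bars hold the central 95% of 10000 random lists matched on signal. The interferon-stimulated point lies at −0.48, −0.55 and −0.72 for Compound C, GSK 690693 and tofacitinib and at −0.04 for doxorubicin, where its sign turns with median centring.

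Doxorubicin gave the largest number of differences from vehicle among the 4 compounds. Immediate early, BMP-responsive and zinc finger transcripts read lower, and those of oxidative phosphorylation and ribosomal proteins higher. At least 2-fold lower were 795 genes, and 164 were at least 2-fold higher. The GTPase gene Rhob was lowest against vehicle (−3.57, 11.9-fold), followed by the matricellular gene Ccn1 (−3.55), the MAP kinase phosphatase gene Dusp1 (−3.37), the transcription factor gene Snai2 (−3.34), Cited2 (−3.11), Myc (−3.09), the EGF receptor inhibitor Errfi1 (−3.06), Id3 (−3.04), Nfkbia (−3.04) and Ankrd49 (−2.87). The higher genes differed less. They were led by Caprin2 (1.95), the proteoglycan gene Lum (1.80), Sox2 (1.71), the chemokine receptor gene Cxcr4 (1.67), Ndrg1 (1.67), the fibroblast activation protease Fap (1.59), Gzmd (1.59), Glrb (1.55), Sprr2g (1.52) and the quinone reductase gene Nqo1 (1.5). Sox2, Gzmd and Sprr2g were dim, at 3.92, 3.82 and 3.91 with vehicle and 5.63, 5.41 and 5.43 with doxorubicin. They reached the filter only on the doxorubicin array. Nqo1 also read above vehicle with Compound C (0.73), GSK 690693 (0.69) and tofacitinib (0.77). With the median of the other 4 arrays as reference in place of vehicle, 59 genes instead of 164 were at least 2-fold higher.

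Interferon-stimulated genes as a list stayed near vehicle with doxorubicin. Their median was −0.04, with 6 of 74 at least 1.5-fold higher and 6 lower, and it was 0.02 after median centring and 0.52 against the median of the other 4 arrays. Trim30d (−1.32), Rtp4 (−1.24) and Irf9 (−0.91) were lower and H2-T23 (1.04) and Ifi27 (1.04) higher. The early IRF3 list had a median of −0.05, which also turned positive with centring, with Gbp5 at 1.05 and Ccl4 at −1.04. Cxcl10 differed by −0.31, Isg15 by −0.31, Ifit1 by −0.48 and Il6 by −0.04. NF-kB dependent genes had a median of 0.13 and a mean of −0.06, with 8 of 44 higher and 8 lower. The lowest of them are genes of the pathway's own inhibitors and regulators, Nfkbia, Nfkbiz (−2.76), Bcl3 (−1.93), the deubiquitinase Tnfaip3 (−1.72) and Rel (−1.51). Among STING pathway components, Trim32 (−1.73), the kinase gene Tbk1 (−1.55) and the DNA sensor gene Cgas (−1.46) were lower, while the 32-gene list had a median of 0.08.

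Of 46 immediate early and MAP kinase feedback genes, 26 were at least 1.5-fold lower with doxorubicin and 5 higher, and the median of −0.83 lay below all 10000 random lists. Jun (−2.65) and Dusp6 (−2.54) were among them, but a second probe set of Dusp6 read 0.12. The BMP list had a median of −0.96, with 13 of 22 lower and 0 higher, including Hes1 (−2.82), Id1 (−2.46), Atoh8 (−2.29) and Smad7 (−2.19). Among 254 zinc finger genes with numbered symbols, 126 were lower and 1 higher, with a median of −0.58 and Zfp281 (−2.67) at the bottom. FOXO targets had a median of −0.38, with Cited2 and Txnip (−2.41) lowest, and the JAK-STAT feedback list one of −0.55 over 19 genes, with Junb at −1.42 and Pim1 at −1.57 on one probe set and −0.08 on another. The p53 target list had a median of −0.24, with 17 of 51 lower and 6 higher. Ddit4 (−2.49), Sesn2 (−2.34), Plk2 (−2.06) and Btg2 (−1.94) were lower and Ndrg1 higher. Mitosis genes had a median of −0.41, with 21 of 60 lower and 0 higher and with the cyclin gene Ccna2 (−1.83) lowest. The DNA replication list had one of −0.16, with E2f8 (−2.35) and Exo1 (−1.74).

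Transcripts of respiration and translation were on the opposite side with doxorubicin. Of 60 oxidative phosphorylation genes, 57 lay above vehicle and 28 were at least 1.5-fold higher, with a median of 0.56. Highest were Ndufa1 (1.37) and Atp5e, at 1.39 on one probe set and 0.13 on another. Ribosomal protein genes had a median of 0.37, with 11 of 54 higher, 1 lower and 50 above vehicle by any amount, and Rpl30 at 1.21. Both medians exceeded all random lists, as did that of glycolysis and hypoxia genes (0.42), in which Adm (−1.43) and Vegfa (−1.08) went the other way. The NRF2 list had a median of 0.44, the lysosome list 0.28 and the unfolded protein response list 0.34, the last with Xbp1 at −1.80. The ATF4 list gave a median of 0.34 but a mean of −0.01, with 10 members higher and 11 lower. Medians were 0.09 for sterol synthesis, with Sqle at −1.53 and Hmgcs1 at −1.32, 0.12 for heat shock, −0.17 for histones, −0.08 for ribosome biogenesis and 0.10 for matrix genes.

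GSK 690693 differed from vehicle by 2-fold in few genes, and interferon-stimulated genes made up 16 of the lower ones. There were 23 genes at least 2-fold higher and 74 at least 2-fold lower, or 12 and 88 after median centring and 11 and 26 against the median of the other 4 arrays. Simulated unchanged arrays with noise drawn from the closest pair averaged 18.32 higher and 18.65 lower genes, and the 23 higher ones are near that number. That pair is GSK 690693 and tofacitinib, so the noise may hold effects of GSK 690693 itself. The simulation therefore does not decide how many of these genes changed. The lowest were the syntrophin gene Sntb1 (−1.87), Cmpk2 (−1.73), Rsad2, which encodes the antiviral enzyme viperin (−1.73), the chemokine gene Cxcl11 (−1.62), the immunity GTPase gene Iigp1 (−1.62), Oasl1 (−1.58), Sytl5 (−1.54), Tspan18 (−1.53), Gpr165 (−1.52) and the costimulatory ligand Cd80 (−1.51). Higher were the aggrecanase gene Adamts5 (2.45, 5.46-fold), the YAP-binding scaffold Amot (1.66), the BMP ligand Gdf6 (1.31), Tuba1b (1.22), Hsdl1 (1.16), S100a7a (1.16), the phosphate transporter Slc20a1 (1.16), the Wnt receptor Fzd3 (1.15), Tnfrsf26 (1.10) and the pentraxin Ptx3 (1.04).

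Of 74 interferon-stimulated genes, 34 were at least 1.5-fold lower with GSK 690693 and 0 higher, and the median of −0.55 lay below all random lists. Gbp7 was at −1.51, Ifit1 at −0.81, Isg15 at −0.73 and Cxcl10 at −0.47. Against the median of the other 4 arrays, which holds Compound C and tofacitinib, the list median was −0.24. The early IRF3 list had a median of −0.54, below all random lists, with 6 of 16 at least 1.5-fold lower, 0 higher and 15 below vehicle, including Ccl4 (−1.42) and Ccl3 (−0.80). NF-kB dependent genes had a median of −0.07, with 1 of 44 higher and 2 lower. The cytokine gene Il6 was 2.03-fold lower (−1.02), and Il1a stood at −0.66 and Mmp3 at 0.59.

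Sterol synthesis, lysosome, ATF4 and ribosome biogenesis genes read higher with GSK 690693 by smaller amounts, and FOXO targets did not stand out by their median. The FOXO list had a median of 0.13, inside the central 95% of random lists. Of its 35 genes 6 were at least 1.5-fold higher and 0 lower, against 296 higher and 395 lower of all 12317 tested genes. At the head of the list were Pdk4 (0.86), Irs1 (0.79, but 0.02 on a second probe set), the ubiquitin ligase gene Fbxo32 (0.75) and the insulin receptor gene Insr (0.64). Sterol synthesis genes had a median of 0.27, with Insig1 (1.02) and Sqle (0.80), and lysosome and autophagy genes also one of 0.27, with Fnip2 (1.0), Rragd (0.82) and Atg14 (0.72). The ATF4 list had a median of 0.23, with Chac1 (1.01) and Slc7a11 (1.01, and 0.39 on a second probe set), and ribosome biogenesis one of 0.25. These last 4 medians exceeded all random lists. The p53 target list had a median of −0.23, below all random lists, although only 4 of 51 genes were at least 1.5-fold lower and 2 higher. By any amount 40 lay below vehicle, among them Cd80 and Eda2r (−0.71). The BMP list (0.01), mitosis genes (0.02), DNA replication genes (0.09), zinc finger genes (0.06), histones (0.07), glycolysis (−0.02), heat shock (0.10), the unfolded protein response (0.08), matrix genes (−0.03), the NRF2 list (0.15), JAK-STAT feedback (0.17) and STING and AMPK components (0.09) lay near vehicle. The signs of the BMP, mitosis and zinc finger medians turned with median centring. Immediate early genes had a median of −0.06, oxidative phosphorylation 0.15 and ribosomal proteins 0.12, and all 3 changed sign (0.10, −0.13 and −0.083) against the median of the other 4 arrays.

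With tofacitinib the interferon-stimulated list had its lowest median of the 4 compounds, and it supplied 27 of the 51 genes that were at least 2-fold lower. At least 2-fold higher were 6 genes. These counts were 87 lower and 1 higher after median centring, and 36 lower and 29 higher against the median of the other 4 arrays. Simulated unchanged arrays with noise drawn from the closest pair averaged 18.32 higher and 18.65 lower genes, more than the 6 higher ones here. The lowest were Usp18, which removes ISG15 from proteins and restrains interferon receptor signalling (−2.77, 6.82-fold), the GTPase genes Iigp1 (−2.74) and Irgm2 (−2.50), Trim30d (−2.44), the oligoadenylate synthetase gene Oas1b (−1.88), the oncostatin M receptor gene Osmr (−1.87), Ifi205 (−1.78), the metalloreductase gene Steap4 (−1.70), Xaf1 (−1.69) and Oas2 (−1.67). Among genes with descriptive symbols, H2ac20 (1.12) and Slc27a3 (1.0) were at least 2-fold higher, and the others higher were small RNA genes.

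Of 74 interferon-stimulated genes, 42 were at least 1.5-fold lower with tofacitinib, 27 at least 2-fold lower and 0 at least 1.5-fold higher. The median was −0.72, or −0.89 after median centring, below all random lists. The brightest early genes differed less, with Cxcl10 at −0.21, Ifit1 at −0.29 and Isg15 at −0.42. The early IRF3 list had a median of −0.22, with 2 of 16 at least 1.5-fold lower and 0 higher, and Ifna4 (−0.70) and Cxcl9 (−0.60) lowest. Its random lists had 1 median in 10000 at or below this value, but against the median of the other 4 arrays the list median was 0.025, on the other side of 0. JAK-STAT feedback and STAT3 or STAT5 target genes had a median of −0.23, below all random lists, with 5 of 19 lower and 0 higher. Besides Osmr these were Socs3 (−1.08, and −0.55 on a second probe set), Cebpd (−1.07), Bcl3 (−1.0) and Stat3 (−0.65). NF-kB dependent genes had a median of 0.01, or −0.17 after median centring, with 3 of 44 higher and 4 lower. Il6 was 1.91-fold lower (−0.93).

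Cell cycle genes read higher with tofacitinib by small amounts. Of 52 DNA replication genes, 8 were at least 1.5-fold higher, 0 lower and 48 above vehicle by any amount, with a median of 0.36 (0.19 after median centring) and with the chromatin assembly gene Chaf1a (0.87) and Gins1 (0.82) highest. Of 60 mitosis genes, 7 were at least 1.5-fold higher, 0 lower and 52 above vehicle by any amount, with a median of 0.29 (0.12 after centring) and Ckap2l (0.90) highest. Both lists exceeded all random lists, as did oxidative phosphorylation (0.25), in which Atp5d read −1.06 on one probe set and 0.11 on another. Ribosome biogenesis had a median of 0.23, lysosome and autophagy 0.18 (−0.08 against the median of the other 4 arrays), and immediate early genes −0.08, the last below all random lists. Positive medians that became negative after centring were those of BMP targets (0.02), FOXO targets (0.03), matrix genes (0.04), p53 targets (0.04), zinc finger genes (0.07), histones (0.08), the unfolded protein response (0.10), the NRF2 list (0.13), ribosomal proteins (0.13), ATF4 targets (0.14), STING and AMPK components (0.14) and sterol synthesis (0.16). The heat shock median was 0.17 and the glycolysis median 0.00, or 0.00 and −0.17 after centring.

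Between compounds, GSK 690693 and tofacitinib were closest, with 59 genes at least 2-fold apart. Interferon genes lay on both sides. Ccl4 (1.78), Cxcl11 (1.49) and Oasl1 (1.46) were higher with tofacitinib than with GSK 690693, as were Gpr165 (1.65) and Trav9d-3 (1.63), while Usp18 (−2.15), Irgm2 (−1.83), Osmr (−1.73), Adamts5 (−2.59) and Ptx3 (−1.44) were lower. The interferon-stimulated list had a median of −0.24 for tofacitinib minus GSK 690693 and the early IRF3 list one of 0.20, with 10 of its 16 genes above 0 and 6 below. After median centring, an alternative added later for these pairs, the early IRF3 value was 0.10. Compound C differed from GSK 690693 by at least 2-fold in 499 genes and from tofacitinib in 748. Tasor (2.79), Rgs4 (2.42), Gtf2b (2.21), Id1 (2.18) and Psmg2 (2.16) were higher with GSK 690693 than with Compound C, and Eid3 (−4.18), Tmem236 (−3.32), Tbc1d8 (−3.08), Csnka2ip (−3.03) and Nr4a1 (−2.51) lower. The Psmg2 value rests on one probe set, and the second was within 0.09 of vehicle with both compounds. The BMP list had medians of 0.67 for GSK 690693 and 0.82 for tofacitinib minus Compound C. The interferon-stimulated list stood at −0.09 for GSK 690693 minus Compound C and −0.22 for tofacitinib minus Compound C, or −0.215 and −0.445 after centring.

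Doxorubicin stood furthest from the other compounds, with 1263 genes at least 2-fold apart from Compound C, 1187 from GSK 690693 and 1090 from tofacitinib. Rhob, Ccn1 and Dusp1 were 14.6-fold, 12-fold and 10.9-fold higher with GSK 690693 than with doxorubicin. Steap4 (−2.88) and Usp18 (−2.74) were the lowest with tofacitinib against doxorubicin. Acod1 (2.16) and Caprin2 (2.14) were higher, and Eid3 (−4.75), Ccn1 (−3.68) and Sesn2 (−3.37) lower, with doxorubicin than with Compound C. Interferon-stimulated genes had a median of 0.50 for doxorubicin minus Compound C, −0.57 for GSK 690693 minus doxorubicin and −0.78 for tofacitinib minus doxorubicin.

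**Figure D3:**
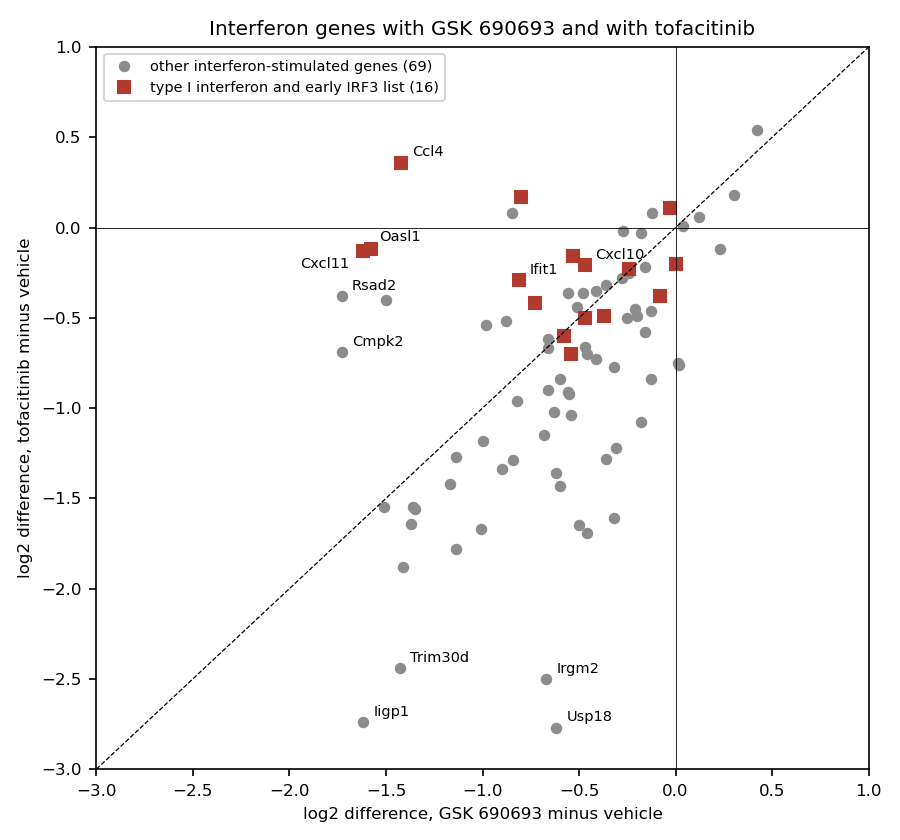
Log2 difference from vehicle with GSK 690693 (horizontal axis) and tofacitinib (vertical axis), 1 point per gene, for 16 type I interferon and early IRF3-dependent genes (squares) and 69 other interferon-stimulated genes (circles). The dashed line marks equal differences. Ccl4, Cxcl11 and Oasl1 lie above it, and Usp18, Irgm2 and Iigp1 below it.

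Trim30d was at least 2-fold lower with all 4 compounds, and 0 genes were at least 2-fold higher with all 4. GSK 690693 and tofacitinib shared 21 lower genes where independent lists would share 0.306. Compound C and GSK 690693 shared 30 against 1.87, Compound C and doxorubicin 73 against 20.1, doxorubicin and GSK 690693 12 against 4.78, Compound C and tofacitinib 7 against 1.29 and doxorubicin and tofacitinib 6 against 3.29. Shared higher genes numbered 12 for Compound C and doxorubicin (2.13 if independent), 7 for doxorubicin and GSK 690693 (0.306), 6 for Compound C and GSK 690693 (0.299), 2 for GSK 690693 and tofacitinib (0.0112), 1 for doxorubicin and tofacitinib (0.0799) and 0 for Compound C and tofacitinib (0.0779). All comparisons share 1 vehicle array that cannot be split, so these values for independent lists are not those of unchanged arrays, and part of each excess may come from the vehicle array. In 100 simulations of unchanged arrays against 1 reference, an overlap averaged 0.01 genes in each direction with normal noise. With noise drawn from the differences between GSK 690693 and tofacitinib, which may hold effects of both compounds, it averaged 6.05 and at most 12 higher genes, and 3.69 and at most 9 lower genes. The simulated lists of that noise averaged 18.32 higher and 18.65 lower genes. The observed lists held between 6 and 164 higher and between 51 and 795 lower genes. Overlap depends on the length of the lists, and tofacitinib with 6 higher genes could not have shared more than 12. The simulated range therefore does not decide for any pair whether its overlap exceeds that of unchanged arrays.

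Across the 12317 genes, which are not independent replicates, the differences from vehicle of GSK 690693 and tofacitinib correlated with r of 0.63. Unchanged arrays compared with one vehicle array gave a simulated r of 0.499 and a covariance of 0.0328. The noise of that simulation was taken from GSK 690693 and tofacitinib as the pair with the smallest standard deviation, so a higher value for this pair, whose covariance was 0.0569, follows by construction and says nothing about shared differences. The observed covariance exceeded the simulated one by 0.0259 for Compound C with doxorubicin (r 0.22), by 0.0155 for Compound C with GSK 690693 (r 0.35) and by 0.0129 for doxorubicin with tofacitinib (r 0.27). It fell short, at −0.0107, for Compound C with tofacitinib (r 0.16) and, at −0.0026, for doxorubicin with GSK 690693 (r 0.17). In differences that share no array, Compound C minus vehicle correlated with GSK 690693 minus tofacitinib with a Pearson r of 0.222 and a Spearman rho of 0.201. With the references exchanged, GSK 690693 minus vehicle correlated with Compound C minus tofacitinib with an r of −0.056 and a rho of −0.094, so the sign depended on which compound was set against vehicle. Over the 74 interferon-stimulated genes alone the first pair had an r of 0.118 and a rho of −0.006 and the second an r of 0.059 and a rho of −0.012. Other pairings gave larger values. Over the same 74 genes, GSK 690693 minus vehicle correlated with Compound C minus doxorubicin with an r of 0.411 and a rho of 0.415 (0.090 and 0.070 over all genes), and tofacitinib minus vehicle with GSK 690693 minus Compound C had the largest r over all genes, 0.261, with 0.069 over the 74.

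As lists, fibroblast markers had a higher median signal than markers of other cell types on all 5 arrays, although levels of different probe sets are only roughly comparable and single genes departed from this. On the vehicle array the muscle marker Acta1 read 10.17 and the neural marker Ncam1 10.74, while the fibroblast markers Fap and Lum read 4.91 and 6.30. The 18 fibroblast marker genes on the array had median signals between 8.62 and 9.09 on the 5 arrays, and 21 macrophage and leukocyte markers between 4.60 and 4.85. Epithelial markers lay between 5.35 and 5.5, endothelial between 4.61 and 4.99, muscle between 5.14 and 5.35, neural between 4.92 and 5.18 and erythroid between 3.91 and 4.16. The medians of the fibroblast list against vehicle were −0.01, 0.18, 0.05 and 0.05 with Compound C, doxorubicin, GSK 690693 and tofacitinib. All but the doxorubicin value changed sign with median centring. In this list Lum and Fap were higher with doxorubicin. With Compound C, Pdgfrb was lower (−1.21), while Fap was higher, at 6.02 against 4.91 with vehicle. Of 7 tested macrophage markers the median was 0.32 with doxorubicin, where Cd68 was at 1.07, and within 0.09 of vehicle with the others. Epithelial (10 tested), muscle (9) and neural (7) lists had medians within 0.24 of vehicle with each compound, and the endothelial (4) and erythroid (0) lists had too few tested members.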

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

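All counts in this part were made after the main comparisons were seen. They concern probe sets that the platform annotation does not list with a gene and that enter no comparison of named genes. Of these, 4847 passed the filter on low values. With Compound C 366 of them differed from vehicle by at least 2-fold, 215 higher and 151 lower. With doxorubicin 635 did, 164 higher and 471 lower. With GSK 690693 there were 153, 87 higher and 66 lower, and with tofacitinib 159, 84 higher and 75 lower. As shares of the 4847 these are 7.55%, 13.1%, 3.16% and 3.28%, against 3.82%, 7.79%, 0.788% and 0.463% of the 12317 named genes tested. The named genes were represented by their probe set with the highest mean, while unlisted probe sets were counted singly. The sets were not matched on signal, so the shares are not directly comparable. No explanation for these probe sets was tested.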

How the results depend on the processing

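The added alternatives, counts without small RNA genes, the doxorubicin array as reference and median centring of 3 lists between compounds, were chosen after the data were seen. Of 114 recomputed gene counts, 91 stayed within 1.5 times the reported count. The interferon-stimulated and NF-kB medians stayed within their bootstrap interval in 62 of 67 recomputations, and the other list medians in 774 of 862. With a 1.5-fold threshold, which counts smaller differences by construction, 747 genes were higher and 1230 lower with Compound C, 1421 and 1750 with doxorubicin, 296 and 395 with GSK 690693 and 328 and 246 with tofacitinib. At that threshold doxorubicin differed from Compound C in 3724 genes, GSK 690693 in 2013 and tofacitinib in 2565, GSK 690693 and tofacitinib differed from doxorubicin in 3418 and 2773, and from each other in 426. Against the median of the other 4 arrays, 59 genes were higher with doxorubicin, 11 higher and 26 lower with GSK 690693 and 29 higher with tofacitinib, and the interferon-stimulated median was −0.14 with Compound C, 0.52 with doxorubicin, −0.24 with GSK 690693 and −0.49 with tofacitinib. That reference is made of treated arrays as well as vehicle. It turned the sign of the early IRF3 (0.025), lysosome (−0.08) and ribosomal protein (−0.075) medians with tofacitinib and of the oxidative phosphorylation (−0.13), immediate early (0.10) and ribosomal protein (−0.083) medians with GSK 690693. Median centring left 12 genes higher with GSK 690693 and 1 higher and 87 lower with tofacitinib, gave an NF-kB median of −0.17 and turned the ribosomal protein median to −0.04 with tofacitinib, by moving all genes alike. Without a filter 17 genes were higher with tofacitinib and the correlation of Compound C minus vehicle with GSK 690693 minus tofacitinib was 0.168. Without small RNA genes 2 were higher with tofacitinib. The mean of the ATF4 list with doxorubicin was −0.0108, where the median was 0.34. Apart from the threshold, the centring and the small RNA genes, the cause was not tested. Of 885 recomputed differences of named genes, 820 moved by no more than the spread of the closest arrays. The other 65 moved by more, 64 of them against the median of the other 4 arrays. No paired analysis was possible because each group has 1 array. Signal over background limits the dim genes, for which no detection call was used here.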

Other observations

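All tests in this part were chosen after the results they concern had been seen. Small nucleolar RNA genes, which guide modification of ribosomal RNA and mostly lie in introns of host genes, read lowest with vehicle. Over 65 such genes the median signal was 7.32 with vehicle, 8.18 with Compound C, 7.90 with doxorubicin, 8.08 with GSK 690693 and 8.01 with tofacitinib. The median difference from vehicle was 0.56, 0.44, 0.50 and 0.39, each above all 10000 random lists, and 60, 50, 58 and 52 of the 65 genes lay above vehicle. By contrast, 94 microRNA genes had medians of −0.05, −0.26, −0.22 and −0.23, of which the last 3 lay below all random lists. The vehicle array stood at least 1.5-fold below all 4 others in 22 genes, and 13 of these were small nucleolar RNA genes. It stood above all others by as much in 23 genes, and the corresponding counts below and above were 397 and 235 for Compound C, 1094 and 189 for doxorubicin, 20 and 9 for GSK 690693 and 35 and 9 for tofacitinib.

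Interferon-stimulated transcripts read lower with Compound C, GSK 690693 and tofacitinib. A vehicle array that alone read these genes high would place doxorubicin below it as well, but that list median was −0.04, and against the doxorubicin array the medians of the 3 compounds were −0.50, −0.57 and −0.78. This argues against the vehicle reading as the whole source, unless the reading of these genes on the doxorubicin array was itself raised by as much. Such a rise, by induction or as a relative excess, stays open. For tofacitinib, lower JAK-STAT signalling may account for the difference, as a hypothesis, since JAK-STAT feedback genes also had a median of −0.23, below all random lists. The same list stood at −0.55 with doxorubicin, where interferon-stimulated genes did not differ as a list, so it is not specific to JAK, and differences between single samples and the unknown doses also stay open.

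With doxorubicin, immediate early and numbered zinc finger transcripts read lower. The scale of the array does not account for this, as the zinc finger median was −0.52 after each array was centred on its median. p53 activation would predict a high median of the p53 target list, which was −0.24. This does not exclude p53 activation, because lower RNA synthesis, considered below, could lower p53 targets whether or not p53 was active. The p53 targets Cdkn1a and Mdm2, named here after their values were seen, read 11.97 and 11.38 with vehicle and 11.30 and 9.96 with doxorubicin. Lower RNA synthesis that leaves long-lived messages in relative excess could give both the lower regulatory transcripts and the ribosomal protein median of 0.37, but RNA synthesis and stability were not measured and the hypothesis rests on the data it was found in.

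By their medians, the early IRF3 genes lay closer to vehicle with tofacitinib than with GSK 690693, and the other interferon-stimulated genes lay further below it. The median for tofacitinib minus GSK 690693 was 0.20 over 16 early genes, with 10 above 0, 6 below and a 95% bootstrap interval over genes of −0.03 to 0.67 that includes 0, and −0.24 over 69 others, or 0.10 and −0.34 after median centring. Compression of bright probe sets would flatten the early genes with either compound, but the 5 early genes at a signal of 10 or more with vehicle (Ccl5, Cxcl10, Ifit1, Isg15 and Oasl1) had a median of −0.73 with GSK 690693 and −0.21 with tofacitinib. The brightest of them, Ccl5 (−0.03) and Cxcl10 (−0.47), differed least with GSK 690693, and the dimmest, Oasl1 (−1.58), most. Compression of the brightest genes is therefore not excluded. Of 10000 random reassignments of membership among the genes of both lists, 11 gave a difference of medians as large as 0.44, a description of these arrays that treats genes as independent. A candidate explanation is that GSK 690693 acts on the step that induces the early genes and tofacitinib on the response to secreted interferon, which was not tested here and cannot be separated from differences between samples with 1 array per group.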
